A study of Mus musculus with 40 samples.

How the data were processed

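Gene expression was measured in 13 tissues of C57BL/6 mice aged 10 to 12 weeks, with 3 arrays for each tissue except islets, which had 4. Per the labels, total RNA was extracted with TRIzol, cleaned on RNeasy columns, copied from random hexamers into labelled sense-strand DNA with biotin, and hybridised to single-channel Affymetrix arrays. The authors processed the arrays with RMA in Affymetrix Expression Console, and the deposited values are RMA signals on a log2 scale, background corrected, normalised between arrays and summarised per probe set. The labels give no version of that program, no sex of the animals, and no statement on whether the arrays of a tissue came from separate animals or whether all 40 arrays were normalised together. P-values therefore measure only the spread between these arrays. Array values carry no counts, and both the number of arrays and signals near background limit the precision.

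The table held 35556 probe sets for 40 arrays, and no column was left without a sample. Probe sets were named from the platform annotation: 21789 had a single gene symbol, 1621 had several symbols and 12146 had none that could be used. Gene IDs matched a mouse RefSeq gene table for 21698 of the named probe sets, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests and were run separately. Where a gene had more than 1 probe set, which applied to 999 genes, the probe set with the highest mean over all arrays was kept. This left 19938 genes, with no filter on dim probe sets. Positions on the genome are not given because the labels name no genome build.

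Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each tissue and a shared residual spread with 27 degrees of freedom, moderated with 8.11 prior degrees of freedom. A gene was taken as selectively high in a tissue when the largest of its 12 one-sided moderated p-values against the other tissues, adjusted by Benjamini and Hochberg over genes within tissue and direction, was under 0.05 and its mean lay at least 1 log2 unit above the mean of every other tissue. The mirror rule defined selectively low genes. The gap of a gene is the difference between its tissue and the nearest other tissue mean. Heart was compared with muscle, islets with pituitary and liver with kidney from the same fit, two-sided, with adjusted p under 0.05 and a difference of at least 1 log2 unit.

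A total of 33 gene lists were tested with camera in limma (inter-gene correlation preset at 0.01, and estimated as an alternative) on the contrast of a tissue against the mean of the other 12 tissues, in 165 list and tissue tests adjusted together. These were adipocyte, brown adipocyte, islet endocrine, exocrine pancreas, islet repressed, neuron, glia, fast skeletal muscle, slow muscle, cardiomyocyte, nephron, hepatocyte, gluconeogenesis and urea cycle, lung epithelium, pituitary endocrine, trophoblast, embryonic blood and yolk sac, enterocyte and gut epithelium, male germ cell, testis soma, thymocyte, thymic stroma, B cell, macrophage, endothelium, stroma, erythroid, immediate early and stress, proliferation, oxidative phosphorylation, fatty acid oxidation, glycolysis and peptide hormone granule. The first 22 were tested in their own tissue and the other 11 in every tissue. Fry, which asks whether a set's genes move on balance in a single direction without comparing them with other genes, was run as a second alternative. Metabolic isoforms and sex-linked genes were followed as levels only. The islet repressed list was drawn partly from work on these samples and is not independent evidence of its direction.

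The comparisons, lists, alternatives and the rule for naming genes were chosen before the data were examined. Named were the 5 selectively high genes per tissue with the largest gap, the 10 selectively low genes of islets and the 3 of every other tissue with the largest gap, the 8 genes per direction of each pair with the largest difference and no overlap between arrays, and up to 4 members per list that passed and 3 that did not. All members of the islet repressed, isoform and sex-linked lists may be named, and genes with predicted names were counted but passed over.

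Alternatives were quantile normalisation applied once more, subtraction of each array's median, array weights (whose estimation stopped before full convergence), a prior with intensity trend and robust estimation, replicate number as a block, every probe set as its own entry, removal of genes whose highest tissue mean lay below the table median of 6.41, minimum differences of 1.5-fold and 4-fold, a rule without a test, fits on a pair's arrays only, and leaving out each array in turn. An alternative without 5 arrays that carried markers of another tissue was added after the data had been seen. The selection rules were tested on simulated data: with a simulated difference of 1.5 log2 units 98% to 100% of the changed genes were recovered, with 3 log2 units 100%, and there were 0 false calls in each run. In these data all tissues shared each gene's mean apart from the simulated difference. Genes with a tissue close behind, near the threshold of 1 log2 unit, were not simulated, so the 0 false calls do not cover them.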

Results

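Transcript levels were measured on 40 arrays from 13 tissues of adult C57BL/6 mice: adipose tissue, pancreatic islets, brain, muscle, heart, kidney, liver, lung, pituitary, placenta, small intestine, testis and thymus. Islets were measured on 4 arrays and every other tissue on 3. Values are RMA signals on a log2 scale and ran from 1.95 to 14.74 over the table, with array medians between 6.296 and 6.58. The tests covered 19938 genes. Folds are ratios of array signals without a detection call, so a fold whose lower mean lies below the table median of 6.41 is to be read as at least that fold. This applies to 50 of the 65 genes named as selectively high and to 41 of the 48 named for the pairs. All values below are tissue means with the standard deviation (SD) between arrays, and n is 3 unless given.

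Arrays of the same tissue resembled each other most. Pearson's r across genes lay between 0.985 and 0.996 within tissues and between 0.580 and 0.930 across tissues, and each of the 40 arrays had its best match in its own tissue. Genes are not independent replicates, so r is given without a p. Heart and muscle were the closest tissues (mean r 0.926), followed by adipose tissue and lung (0.905) and by islets and pituitary (0.904). Testis stood farthest from every other tissue, with its highest mean r of 0.681 reached against thymus.

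The first question was which genes mark each tissue of the panel. In total 5219 genes were selectively high, 26.2% of those tested, and 505 were selectively low, 2.53%. Testis held the most selectively high genes (1793), then brain (748), small intestine (423), thymus (359), placenta (320), liver (311), lung (251), kidney (238), muscle (189), adipose tissue (181), islets (162), heart (144) and pituitary (100). The median gap to the nearest tissue was largest in liver, with 2.70 log2 units, and smallest in heart, with 1.31. Of the genes named by the rule as selectively high, Gh in pituitary had the largest adjusted p, 3.5e-11.

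**Figure D1:**
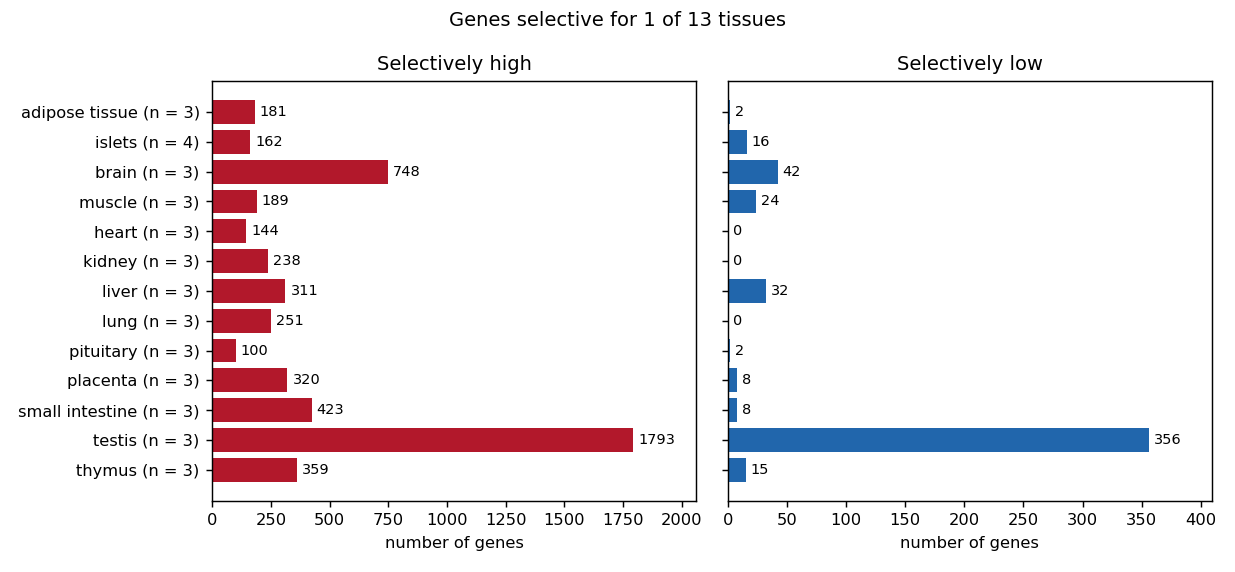
Number of genes selectively high (left) and selectively low (right) in each tissue, with the number of arrays in brackets. The bars start at 0 and the horizontal scales differ between the panels, since testis reaches 1793 genes on the left and 356 on the right, and heart, kidney and lung have 0 on the right.

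Islets were marked by hormone genes and by the machinery of insulin storage and glucose handling. Iapp, which encodes islet amyloid polypeptide, measured 14.11 ± 0.023 (n = 4) against 4.83 ± 0.22 in the nearest tissue, thymus, a 623-fold gap. G6pc2, an islet glucose-6-phosphatase, reached 12.82 ± 0.094 (233-fold), Slc30a8, the zinc transporter of insulin granules, 12.51 ± 0.053 (175-fold), Ins2, an insulin gene, 12.999 ± 0.073 (114-fold), and Gcg, the glucagon gene, 13.76 ± 0.11 (n = 4), 105-fold above small intestine. Of 27 measured islet endocrine genes, 21 were selectively high. Slc2a2, the glucose transporter GLUT2, was not among them, because small intestine (11.84 ± 0.062) lay near the islet level of 12.53 ± 0.15, and Pcsk1, a prohormone convertase, stood at 12.39 ± 0.17 in islets and 11.67 in pituitary. Transcripts of digestive enzymes were also abundant in the islet arrays: 14 of 17 measured exocrine pancreas genes were selectively high there, by a mean of 5.99 log2 units over the other tissues for the whole list. Among them Try4, Pnliprp1, Cel and Cela3b exceeded their nearest tissue, small intestine, between 48.0-fold and 55.4-fold. Without small intestine replicate 3 the gap rose to 89.1-fold for Pnliprp1 and 82.6-fold for Cel. Ptf1a, the transcription factor of acinar cells, measured 5.39 ± 0.14 in islets and was not selective. Whether acinar cells were present in the islet samples was not tested. In islets the 17 exocrine pancreas genes averaged 11.72 and the 27 islet endocrine genes 11.57, though on different probe sets. The count of genes selectively high in islets includes the 14 exocrine pancreas genes. It also includes genes outside that list, among them Ctrl, Gp2, Reg2 and Try10, which were higher on the same small intestine arrays as the digestive enzyme genes. The 14 may therefore understate how many of the genes counted in islets go with the digestive enzymes.

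Adipose tissue was led by secreted adipocyte products. Adipoq, the adiponectin gene, was 46.4-fold above thymus, Lep, the leptin gene, reached 11.03 ± 0.18 and was 41.0-fold above muscle, and Retn, the resistin gene, measured 13.23 ± 0.055, 40.9-fold above thymus. Tshr, the thyrotropin receptor, and Aoc3, an amine oxidase of adipocytes, were 32.7-fold and 28.0-fold above their nearest tissues. On thymus replicates 1, 2 and 3 Adipoq was 8.79, 7.01 and 6.82. Of 20 measured adipocyte genes 12 were selectively high, while Cd36, Lpl and Scd1 had their highest mean in adipose tissue but lay within 1 log2 unit of heart or liver. No brown adipocyte gene was selectively high in adipose tissue (0 of 10 by limma, and 0 also at an unadjusted p under 0.05, since 0 had their highest mean there). That list differed by -0.34 log2 units from the other tissues (camera adjusted p = 0.224, 0.552 with an estimated correlation), whereas fry gave an adjusted p of 7.09e-05 for lower values. Ucp1, the uncoupling protein of brown fat, measured 4.95 ± 0.019. Of the 10 members 5 had their highest mean in heart, so the rule could not call them in adipose tissue whatever cells it held. Cox8b, for example, measured 8.81, 7.99 and 8.19 in adipose tissue and 12.71, 12.44 and 12.46 in heart. The count of 0 therefore cannot decide whether brown adipocytes were present.

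Muscle and heart were marked by genes of fast skeletal muscle and of cardiomyocytes. Muscle was led by the fast myosins Myh4 (13.70 ± 0.045, 321-fold above its nearest tissue), Myh1 (177-fold) and Myh2 (120-fold), by the calcium pump Atp2a1 (169-fold above heart) and by the troponin gene Tnnc2 (136-fold). Of 21 fast skeletal muscle genes, 20 were selectively high in muscle. Heart was led by the natriuretic peptide gene Nppa (13.23 ± 0.30, 101-fold), the calcium pump regulator Pln (97.1-fold), Mybpc3 (82.6-fold), the myosin Myh6 (66.9-fold) and the troponin gene Tnnt2 (45.8-fold), and 17 of 21 cardiomyocyte genes were selectively high there. The nearest tissue for Myh6 and Tnnt2 was lung, whose replicate 2 measured 8.87 for Myh6 against 7.22 and 6.79 in the other arrays. Slow muscle genes were shared: 3 of 9 (Tnni1, Tnnt1 and Myh7) were selectively high in muscle, and 5, among them Tnnc1, Myl2 and Myl3, in heart. Myl2 and Myl3 are also in the cardiomyocyte list.

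Brain was led by neuronal genes. Vxn, a gene of neuronal differentiation, was 62.6-fold above its nearest tissue, Cnksr2, a synaptic scaffold, 50.9-fold, Grm3, a glutamate receptor, 44.8-fold, Cplx1, a regulator of vesicle release, 41.5-fold, and Lamp5 40.6-fold. Of 18 neuron genes 16 were selectively high, with Nefl, Neurod6, Grin2b and Slc17a7 at the top, and of 15 glia genes 11 were, including Mobp, Slc1a2, Gfap and Gjb6. Gad1, an enzyme of GABA synthesis, missed the threshold because islets measured 9.02 against 9.92 ± 0.062 in brain. For 34.9% of the genes selectively high in brain, 261 genes, the nearest tissue was pituitary.

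Pituitary was led by its hormones. Cga, the shared subunit of the glycoprotein hormones, measured 13.87 ± 0.062 (327-fold), Prl, the prolactin gene, 13.90 ± 0.088 (326-fold), Pomc 13.32 ± 0.12 (126-fold), Fshb 12.03 ± 0.28 (93.1-fold) and Gh, the growth hormone gene, 14.23 ± 0.054 (68.1-fold). Brain was the nearest tissue for Gh and Prl, with means of 8.14 ± 2.64 and 5.55 ± 1.71, and brain replicate 1 held Gh at 11.004 and Prl at 7.52. Without that array the folds rose to 184 for Gh and 645 for Prl, and without brain replicate 3 the fold of Gh fell to 30.3. Of 18 measured pituitary endocrine genes 15 were selectively high.

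Liver, kidney, small intestine and lung were marked by genes of their epithelial cells. In liver the major urinary protein gene Mup3 (13.01 ± 0.15, 307-fold) led the genes of conjugation and drug metabolism Ugt2b1 (286-fold), Ces1c (276-fold), Sult2a8 (265-fold) and Cyp2c50 (226-fold), and 18 of 25 hepatocyte genes were selectively high. In kidney the transporter genes Slc7a13 (13.02, 254-fold), Slc12a1 (187-fold) and Slc22a19 (125-fold), the tubular glycoprotein gene Umod (187-fold) and Akr1c21 (143-fold) led, and 15 of 17 nephron genes passed. Small intestine was led by the brush border enzyme gene Sis (12.84 ± 0.16, 411-fold), Adh6a (252-fold), Cyp2c65 (217-fold), Clca4b (217-fold) and the cadherin gene Cdh17 (201-fold), and 19 of 24 gut epithelium genes passed. In lung the chemokine gene Cxcl15 (13.39 ± 0.10, 580-fold), the surfactant genes Sftpc (354-fold) and Sftpa1 (143-fold), the club cell gene Scgb1a1 (183-fold) and Lamp3 (122-fold) led, and 15 of 19 lung epithelium genes passed. Gluconeogenesis and urea cycle genes were selectively high in liver for 3 of 10 members (Arg1, Cps1 and Otc), while Pck1 and Pcx were higher in adipose tissue and Fbp1 in kidney. Digestive enzyme transcripts were present in small intestine replicates 1 and 3, with Cpa1 at 8.77 and 10.00, and lower in replicate 2, with 6.27.

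**Figure D2:**
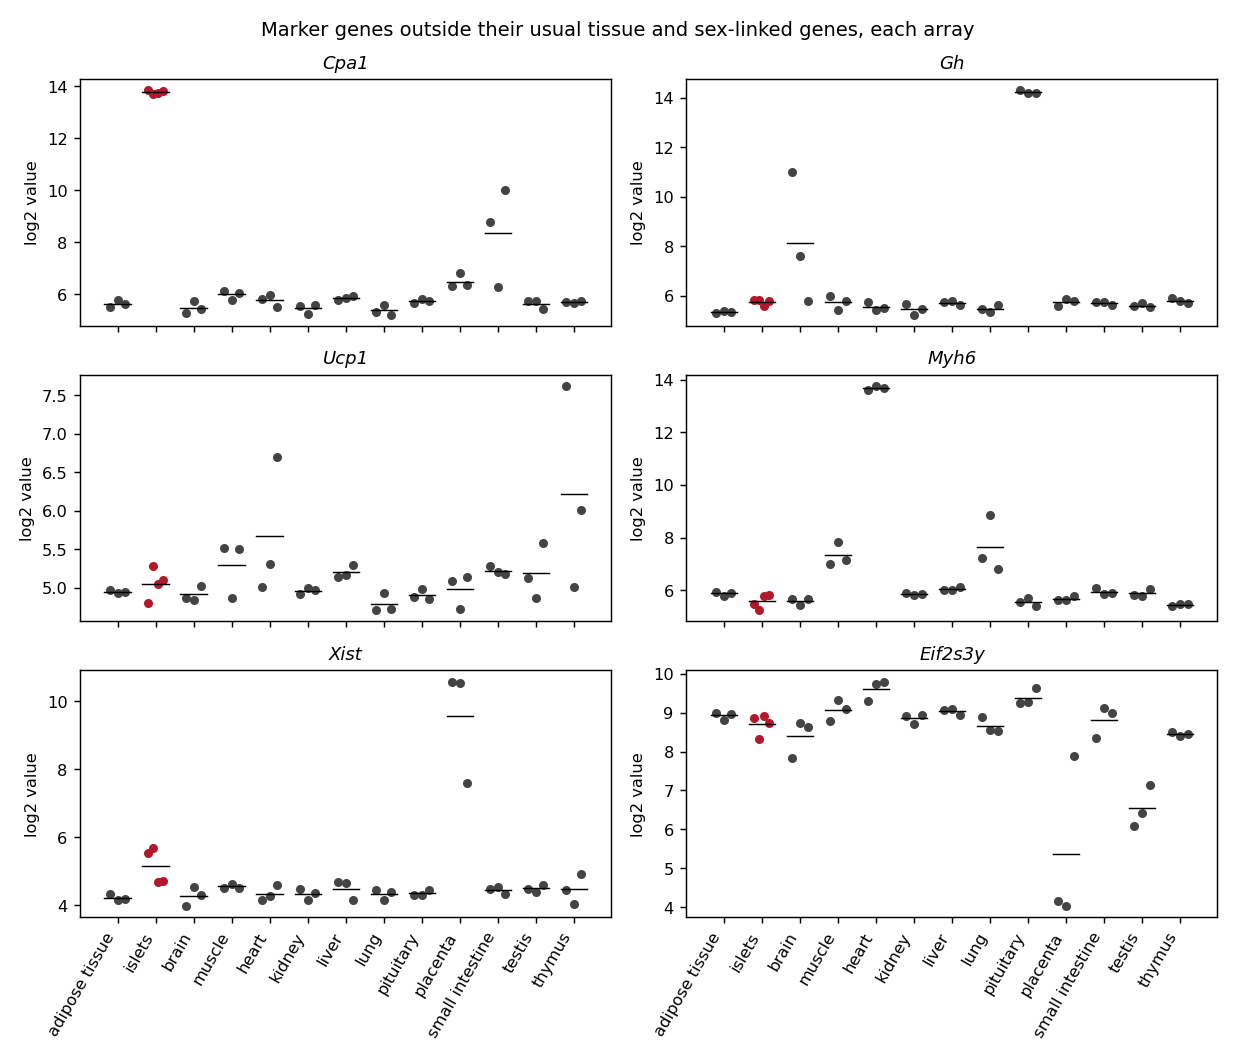
Log2 value on each array (points, islets in red, line at the tissue mean) of the digestive enzyme gene Cpa1, of Gh, of the brown fat gene Ucp1, of the cardiac myosin Myh6, of Xist, which is transcribed from an inactive X chromosome, and of the Y-linked gene Eif2s3y. Cpa1 is raised on small intestine replicates 1 (8.77) and 3 (10.00), Gh on brain replicates 1 (11.004) and 2 (7.62), Ucp1 on thymus replicates 1 (7.62) and 3 (6.01) and heart replicate 3 (6.70) and Myh6 on lung replicate 2 (8.87), and Xist stands apart on all 3 placenta arrays.

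Placenta, testis and thymus were marked by genes of trophoblast, germ cells and thymocytes. Placenta was led by the prolactin family genes Prl2b1 (12.94 ± 0.21, 804-fold) and Prl8a9 (637-fold), the trophoblast gene Tpbpb (637-fold) and the adhesion molecule genes Ceacam5 (603-fold) and Ceacam14 (578-fold). Of 22 trophoblast genes 19 were selectively high, as were 3 of 4 genes of embryonic blood and yolk sac, namely the embryonic globins Hbb-y and Hba-x and the fetal albumin-like gene Afp. Testis was led by the glycerol kinase gene Gk2 (12.33 ± 0.27, 238-fold), Mael of the piRNA pathway (190-fold), Fabp9 (181-fold), the transition protein gene Tnp2 (156-fold) and Akap3 of the sperm tail (138-fold). Of 22 male germ cell genes 20 were selectively high, against 3 of 8 genes of the testis soma (Hsd17b3, Cyp17a1 and Fshr). Star, Cyp11a1 and Clu, also of the soma list, lay within 1 log2 unit of placenta or liver. Thymus was led by genes of antigen receptor rearrangement, Rag1 (13.15 ± 0.048, 203-fold), Dntt (110-fold) and Rag2 (33.7-fold), with Prss16, a protease of the thymic cortex (52.6-fold), and Themis, a signalling gene of developing T cells (47.9-fold). Of 21 thymocyte genes 19 were selectively high, and 4 of 7 thymic stroma genes.

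In camera 21 of the 22 lists tested in their own tissue passed, with adjusted p between 2.55e-33 and 6.88e-05, and 0 of them were lost with an estimated correlation. The exception was the brown adipocyte list. The lists that passed include the islet repressed list, which was drawn partly from work on these samples. Some lists share members and are not separate evidence. The slow muscle and cardiomyocyte lists share Myl2 and Myl3 among others. The hepatocyte list shares Cps1, Otc and Pck1 with the gluconeogenesis and urea cycle list. The counts of selective members were the same when adjusted over the list alone as over all genes.

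**Figure D3:**
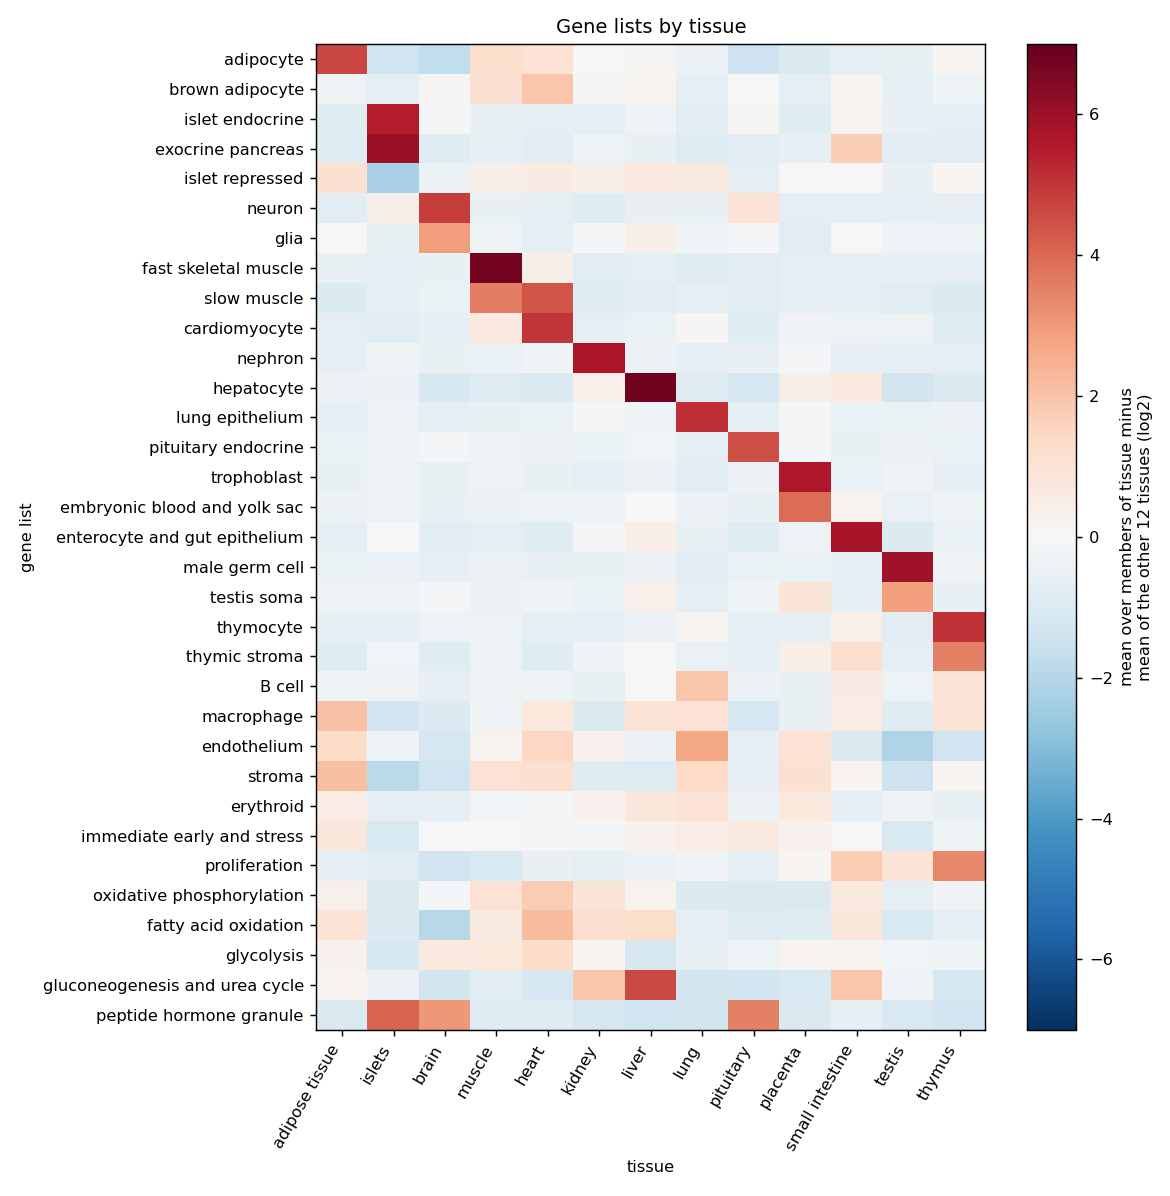
Mean over the members of each gene list of the level in a tissue minus the mean of the other 12 tissues, in log2 units (red higher, blue lower). Most lists stand out in their own tissue, from 2.89 for testis soma to 6.74 for hepatocyte genes in liver. Outside their own tissue, slow muscle genes are higher in heart (4.404), brown adipocyte genes in heart (1.94) and exocrine pancreas genes in small intestine (1.75). Gluconeogenesis and urea cycle genes are also higher in small intestine (1.93) and kidney (1.92). Islet repressed genes, a list not independent of these samples, are lower in islets (-2.29).

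The reverse question was which genes are lower in a single tissue than in all others. Of the 505 selectively low genes 356 were in testis, 42 in brain, 32 in liver, 24 in muscle, 16 in islets, 15 in thymus, 8 each in placenta and small intestine, and 2 each in adipose tissue and pituitary. In 470 of them all 12 other tissues lay above the table median. A 4-fold gap was reached by 41 of them, against 2561 of the 5219 selectively high genes. Heart, kidney and lung had 0 such genes by limma. At an unadjusted p under 0.05 there were 87 genes in heart, 54 in kidney and 241 in lung, none of them 2-fold, and the rule without a test also gave 0.

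In islets, 16 genes were selectively low. Slc16a1, which encodes the lactate and pyruvate carrier MCT1 (probe set 10495035), measured 5.35 ± 0.40 (n = 4) against 7.85 ± 0.30 in the nearest tissue, pituitary, 5.66-fold lower. Ldha, the lactate dehydrogenase subunit of muscle type (probe set 10553301), measured 8.17 ± 0.11 (n = 4) against 10.13 ± 0.067 in pituitary, 3.89-fold lower. Oat, ornithine aminotransferase (probe set 10568568), stood at 6.65 ± 0.18 (n = 4) and was 4.27-fold below testis, and Pdgfra, a growth factor receptor of mesenchymal cells (probe set 10522503), stood at 5.47 ± 0.18 (n = 4) and was 4.26-fold below liver. The adjusted p of these genes lay between 7.01e-20 for Oat and 1.9e-14 for Slc16a1. The kinase gene Stk17b was 3.41-fold lower than its nearest tissue, the mitochondrial gene Higd1a 2.99-fold, the matrix gene Prelp 2.64-fold, the phospholipase gene Pla2g7 2.51-fold, the endocytosis gene Eps15 2.42-fold and the matrix protease gene Mmp14 2.09-fold. The other 6 were Notch2, Mme, Pop4, Sulf2, Zfp36l1 and Epb41l2, between 2.01-fold and 2.09-fold, and they are named here after their values were seen.

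Genes of the islet repressed list were lower in islets, with a mean difference of -2.29 log2 units (camera adjusted p = 2.4e-12, 0.00198 with an estimated correlation). The list was drawn partly from work on these samples, so these p-values are not independent evidence of its direction. Of its 21 members 15 had their lowest mean in islets and 5 were selectively low: Slc16a1, Oat, Pdgfra, Ldha and Zfp36l1. Igfbp4, a binding protein of insulin-like growth factors, and Cxcl12, a chemokine of stromal cells, were lowest in islets by gaps of 0.94 and 0.89, short of 2-fold, and so were Acot7 (0.76) and Mgst1 (0.71). Rest, a repressor of neuronal genes, measured 5.79 ± 0.30 in islets and 5.76 ± 0.26 in brain. Hk1, a hexokinase, measured 12.50 ± 0.10 in islets and was lowest in testis on the probe set used. Its tissue means there ran only from 11.91 in testis to 12.99 in thymus. Hk1 has 1 other probe set, whose values are not given here, so its level in islets rests on a nearly flat signal. Cd59a (8.72, lowest in thymus) and Dapp1 (6.94, lowest in liver) stood above the mean of the other tissues in islets, by 0.641 and 0.082 log2 units. The islet arrays also stood lower in stroma genes (-1.91, adjusted p = 7.49e-09, 0.0289 with an estimated correlation), with Pdgfra a member of both lists. The second probe set of Higd1a had a gap of -0.019 log2 units, so its lowest mean was not in islets, and the call rests on the other probe set. The call of Mmp14 ended without brain replicate 1, where its gap fell to 0.92 log2 units, and with array weights, where it was 0.94.

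**Figure D4:**
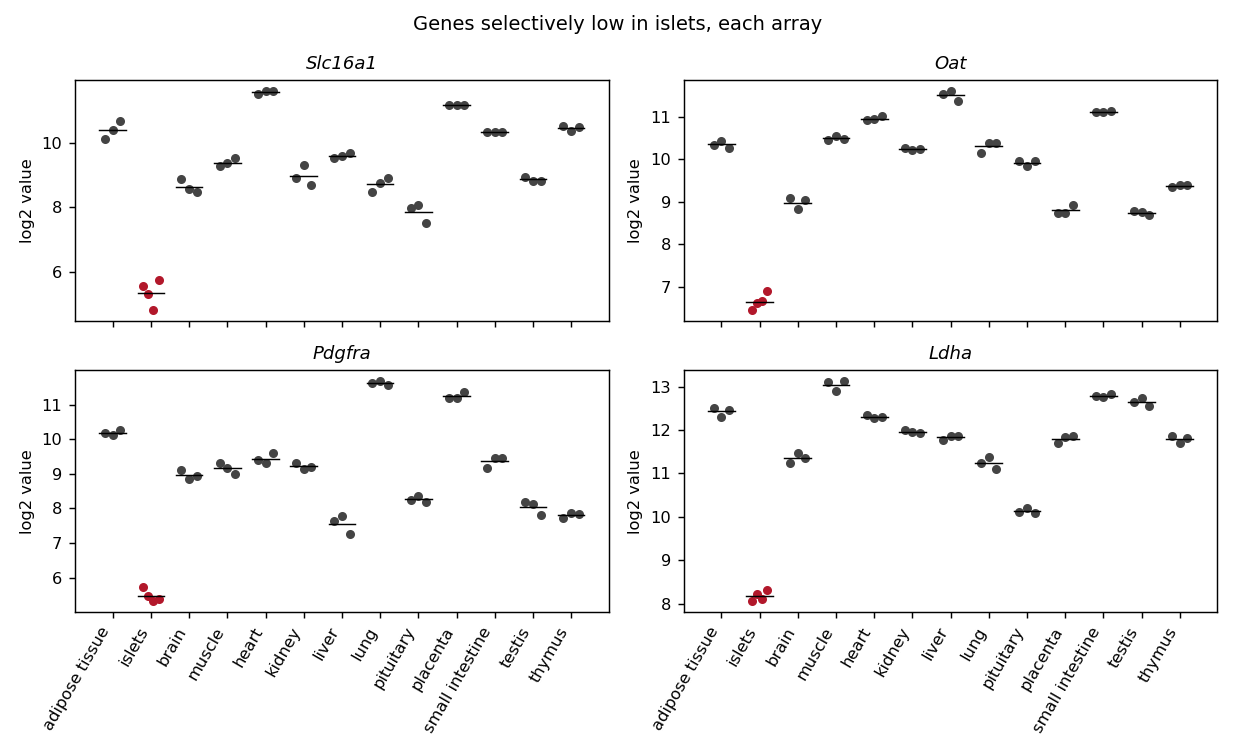
Log2 value of Slc16a1, Oat, Pdgfra and Ldha on each array (points, islets in red) with the mean of each tissue (line), for 4 islet arrays and 3 arrays of each other tissue. All islet arrays lie below all arrays of the other tissues, and pituitary is nearest for Slc16a1 and Ldha.

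In testis the largest gaps among the named low genes were those of Malat1, Ddx3x and Atrx. Malat1, an abundant nuclear noncoding RNA, measured 7.44 ± 0.43 against 11.20 ± 0.34 in liver, the nearest tissue, a 13.6-fold gap. The X-linked genes Ddx3x, an RNA helicase, and Atrx, a chromatin remodeller, were 8.21-fold and 8.12-fold lower, and a second probe set of Ddx3x gave a gap of 3.70 log2 units. Testis held 34 of the 41 genes with a 4-fold gap.

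Brain was low in Serping1, the complement inhibitor (6.73 ± 0.71, 5.20-fold), Adh1, an alcohol dehydrogenase (3.62-fold), and Txnip, a regulator of glucose uptake (3.39-fold). Liver was low in the tetraspanin genes Tspan3 (7.40 ± 0.19, 5.26-fold) and Tspan13 (4.67-fold) and in Slc25a4, the muscle and heart type of the mitochondrial ADP/ATP carrier (3.81-fold). Muscle was low in the chaperone genes Hsp90aa1 (9.51 ± 0.13, 3.77-fold) and Pdia3 (2.77-fold) and in Abhd2 (2.55-fold), and the remaining probe sets of Hsp90aa1 gave gaps of 1.86 and 1.89 log2 units. Thymus was low in Fam135a (4.51-fold), in the tight junction gene Tjp1 (2.99-fold) and in Slc35f5 (2.66-fold). Placenta was low in Enpp4 (2.84-fold), the nuclear receptor coactivator Ncoa1 (2.55-fold) and the coenzyme A synthesis gene Pank1 (2.53-fold). Small intestine was low in the cytoskeletal linker Rdx (2.94-fold), the heat shock factor Hsf2 (2.86-fold) and Camsap2 (2.34-fold). In adipose tissue Hook1, of vesicle transport (3.92-fold), and Retreg1, an endoplasmic reticulum receptor of autophagy (2.38-fold), were low. In pituitary Nudt4 (2.41-fold) and Rras2, a Ras relative (2.01-fold, 1.01 log2 units), were low. The call of Rras2 ended with array medians subtracted (0.98), without islets replicate 3 (0.95) and without pituitary replicate 1 (0.98), which left 1 gene in pituitary. The largest adjusted p among the low genes named by the rule was 7.43e-07, for Txnip.

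Isoforms of glucose and lactate handling differed between tissues, each probe set being compared only with itself. The glucose transporter Slc2a1 was selectively high in placenta (12.89) and Slc2a3 in testis (12.90), Slc2a4 was highest in muscle (11.78) and heart (11.38), and Slc2a2 in islets (12.53), small intestine (11.84) and liver (11.59). The lactate dehydrogenase Ldhc was selectively high in testis (12.37) and the lactate exporter Slc16a3 in muscle (11.48). Pkm, a pyruvate kinase, was selectively low in liver (8.52). In islets Ldha and Slc16a1 were selectively low. The Hk1 probe set used, which was nearly flat over the tissues, differed by 0.016 log2 units from the mean of the other tissues. Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, was highest in kidney (11.22) and liver (10.999), and Cpt1c in testis (9.92) and brain (9.16).

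**Figure D5:**
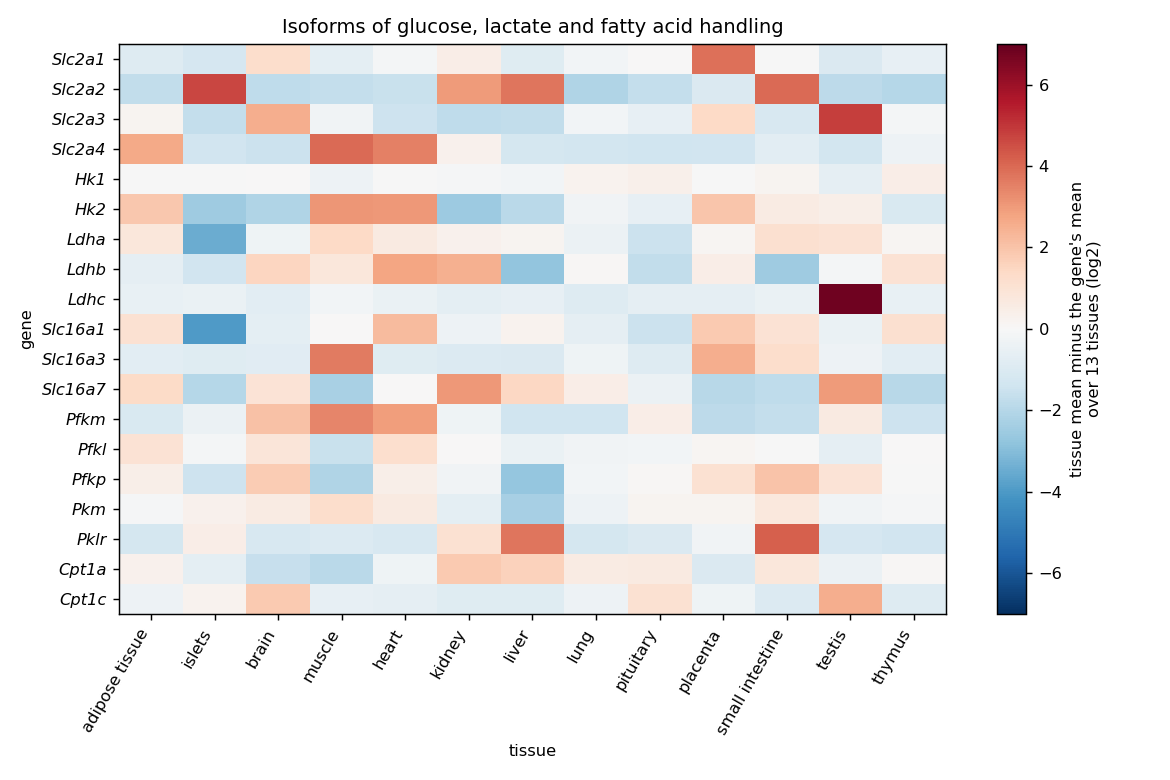
Tissue mean minus the gene's mean over the 13 tissues (log2 units, red higher, blue lower) for 19 genes of glucose, lactate and fatty acid handling. Ldha (8.17) and Slc16a1 (5.35) are lowest in islets, Ldhc is highest in testis (12.37), Slc16a3 in muscle (11.48) and Slc2a1 in placenta (12.89).

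Heart and muscle were compared to ask which genes part striated muscles of different function. In heart 1415 genes were higher and in muscle 658. Pln was 223-fold higher in heart (13.90 ± 0.041 against 6.10 ± 0.21), Nppa 132-fold, Tnnt2 88.1-fold, Mybpc3 84.1-fold, Tecrl, a gene of cardiac rhythm, 84.0-fold, Myh6 82.7-fold, Fhl2 80.0-fold and Tnni3 72.1-fold. Myh4 was 342-fold higher in muscle, the calcium buffer gene Pvalb 223-fold, Myh1 193-fold, Actn3 171-fold, Tnnc2 170-fold, Atp2a1 169-fold, Tnnt3 139-fold and Ampd1 123-fold. Fatty acid oxidation genes were higher in heart for 14 of 15 members, oxidative phosphorylation genes for 3 of 25, and endothelium and macrophage genes for 7 of 11 each. Of the slow muscle list, 6 genes were higher in heart and 3 in muscle. Ldhb was higher in heart by 1.93 log2 units, and Slc16a3 differed by -4.47, being higher in muscle.

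Islets and pituitary, both peptide hormone tissues, were compared to ask what separates them. In islets 784 genes were higher and in pituitary 1196. Higher in islets were Iapp (989-fold), Gcg (436-fold), the enzyme gene Cpb1 (431-fold), G6pc2 (346-fold), the lipase-related gene Pnliprp1 (302-fold), the carboxypeptidase gene Cpa1 (264-fold), Cltrn, the collectrin gene (250-fold), and Slc30a8 (211-fold). Higher in pituitary were Prl (750-fold), Cga (443-fold), Gh (356-fold), Fshb (129-fold), Pomc (126-fold), Cyp2f2 (81.2-fold), Oacyl (57.4-fold) and the growth regulator Dlk1 (55.9-fold). Islet endocrine genes were higher in islets for 25 of 27 members and exocrine pancreas genes for 16 of 17. The 784 genes thus include digestive enzyme genes, among them Cpb1, Pnliprp1 and Cpa1. Whether these transcripts came from acinar cells in the islet samples was not tested. Of 15 peptide hormone granule genes, 4 were higher in islets and 1 in pituitary, with a median difference of 0.523 log2 units toward islets. Pituitary was higher in 13 of 21 islet repressed genes, 6 of 14 stroma genes and 7 of 14 immediate early and stress genes.

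Liver and kidney were compared as metabolic organs that share gluconeogenesis. In liver 960 genes were higher and in kidney 1607. Mup3 was 561-fold higher in liver, the cytochrome gene Cyp3a11 513-fold, Ces1c 397-fold, Ugt2b1 392-fold, the plasma protein gene Ahsg 372-fold, the fatty acid carrier Fabp1 358-fold, Tdo2, of tryptophan breakdown, 304-fold and Sult2a8 293-fold. In kidney Cltrn was 504-fold higher, the androgen-regulated gene Kap 473-fold, Slc7a13 322-fold, the brush border protease Mep1a 254-fold, Umod 237-fold, Slc12a1 204-fold, the sulfate transporter Slc13a1 174-fold and the phosphate transporter Slc34a1 150-fold. Hepatocyte genes were higher in liver for 22 of 25 members and macrophage genes for 9 of 11. Nephron genes were higher in kidney for 16 of 17 members and glycolysis genes for 5 of 12, while gluconeogenesis and urea cycle genes were higher in liver for 4 of 10. Over the 3 pairs the largest adjusted p of a named gene was 4.46e-17, for Gh.

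The mean levels of oxidative phosphorylation and fatty acid oxidation genes were highest in heart. Oxidative phosphorylation genes were higher in heart than in the other tissues by 1.78 log2 units, with 25 of 25 members highest there (adjusted p = 8.61e-24, 0.00196 with an estimated correlation), and Ndufa9 and Ndufs1 were selectively high. They were also higher in muscle (1.03) and kidney (0.90), both with adjusted p = 0.0126 with an estimated correlation, and lower in islets (-1.04), lung (-0.98), pituitary (-1.005) and placenta (-1.04). Fatty acid oxidation genes were higher in heart by 2.23 log2 units, 13 of 15 members highest there, with Hadhb, Acadl, Hadha and Etfdh among 6 selectively high genes (adjusted p = 0.0212 with an estimated correlation). In brain they were lower by preset correlation (-1.92), a call lost with adjusted p = 0.0835 with an estimated correlation. Glycolysis genes were higher in heart by the mean (1.28, median 1.05, adjusted p = 0.0289 with an estimated correlation), but 7 of 12 members were highest in muscle and 2 in heart, and the median difference was larger in muscle (1.40, mean 0.76, adjusted p = 0.214 with an estimated correlation). Their lower levels in liver (-1.12, Aldoa and Pkm selectively low) and islets (-1.10, Ldha selectively low) had adjusted p = 0.269 and 0.153 with an estimated correlation.

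Cell cycle genes were highest in thymus, and granule genes in islets. Proliferation genes were highest in thymus for 15 of 15 members (3.36 log2 units, adjusted p = 0.00254 with an estimated correlation), with Mcm2, Ccna2, Mcm5 and Mcm3 among 11 selectively high genes, and were higher in small intestine by 1.76 (adjusted p = 0.0191 with an estimated correlation). In testis (0.95) and brain (-1.32) the calls were lost, with adjusted p = 0.238 and 0.0993 with an estimated correlation. Peptide hormone granule genes were higher in islets (4.05), pituitary (3.52) and brain (3.05), with adjusted p of 0.000303, 0.000359 and 0.00111 with an estimated correlation, and Chga and Scg3 were selectively high in islets and Vgf and Rab3a in brain.

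Genes of cells that any tissue holds also differed. Endothelium genes were higher in lung by 2.72 log2 units, with 9 of 11 highest there and Vwf, Tek, Eng and Pecam1 among 5 selectively high (adjusted p = 0.00862 with an estimated correlation), and in heart (1.47) and adipose tissue (1.29). In testis 10 of 11 were lowest (-2.12), a call lost with adjusted p = 0.129 with an estimated correlation. Macrophage genes were higher in adipose tissue (2.07, adjusted p = 0.0289 with an estimated correlation), and their lower level in islets (-1.36) was lost with adjusted p = 0.196. Stroma genes were higher in adipose tissue (2.09, adjusted p = 0.0128 with an estimated correlation). B cell genes were higher in lung (1.97), with Ms4a1 and Cd79a selectively high, a call lost with adjusted p = 0.108 with an estimated correlation. Immediate early and stress genes were higher in adipose tissue (0.77) and lower in islets (-1.05), both lost, with adjusted p = 0.328 and 0.323 with an estimated correlation, and their mean on the 3 adipose arrays ranged from 7.84 to 9.31. Erythroid genes, with 4 measured, passed in 0 of 13 tissues by camera (1 at an unadjusted p under 0.05, and 11 by fry). Over all 165 tests 111 passed with the preset correlation, and 46 of these held with an estimated one.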

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

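The tests on growth hormone and prolactin transcripts in brain, and the count outside the exocrine pancreas list in small intestine, were chosen only after the result was seen.

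On the 4 islet arrays, 4 of 128 tested values had an array far from the others, where chance gives about 1 in 20. Pkm was 11.04 on replicate 4 and between 11.14 and 11.15 on the others (a gap of 0.914 of the range). Sytl4 was 10.75 on replicate 4 and between 11.02 and 11.06 on the others (0.869), and the mean of the islet endocrine list was 11.52 there and between 11.58 and 11.59 on the others (0.905). The mean of the slow muscle list was 6.74 on replicate 1 and between 6.59 and 6.61 on the others (0.890).

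Probe sets outside the gene tests also marked tissues. Of 12146 probe sets without a usable gene name, 1048 were selectively high, with 212 in brain, 173 in testis, 150 in islets, 148 in thymus and 110 in small intestine. Another 383 were selectively low, 363 of them in testis. Of 1621 probe sets with several symbols, 524 were selectively high, with 130 in testis, 116 in islets and 114 in thymus.

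For the 16 genes selectively low in islets, of which Pdgfra is in the stroma list, a low share of stromal cells was weighed against scaling between arrays. On scaling, 16 of 16 kept their call after quantile normalisation and after subtraction of array medians. The islet arrays had medians from 6.495 to 6.578, higher than most other arrays, so subtraction lowers islets against most tissues. Both alternatives gave more low genes in islets, so they could hardly remove these calls, and scaling stays open. A low share of stromal cells in the islet samples may contribute: over the other 12 tissues the genes' median r with the mean of the stroma list was 0.410, above the 95th percentile (0.301) of 10000 random sets matched in level, and the 14 stroma genes averaged 6.72 in islets, with Dcn at 7.10 against 13.22 in adipose tissue. This covers the genes unevenly, as r was over 0.5 for Prelp, Pdgfra, Mmp14, Notch2, Slc16a1 and Epb41l2 and lower for the other 10, including Ldha (0.242), Oat (0.265), Eps15 (0.092) and Pop4 (-0.103). Repression in the islet cells themselves stays open as untested.

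In small intestine, 17 genes were at least 1 log2 unit higher on replicates 1 and 3 than on replicate 2, for example Cpb1 with 8.96 and 10.14 against 5.91 (chosen after its values were seen). These are 0.0853% of all genes, and 1 gene was lower. The values had been normalised between arrays, which removes a shift shared by all genes, so the count cannot decide on such a shift. It argues only against a difference of this size in many genes that remained after normalisation. Pancreas tissue in the sample may be the source: 14 of the 17 (82.4%) had their highest mean in islets, against 8.98% of all genes. As 9 of the 17 are exocrine pancreas genes, which prompted the test, the other 8 were also counted apart. Of these, 5 (62.5%) were highest in islets, against 8.92% of genes outside that list, the exceptions being Cyp2c29, Cyp2c55 and Ubd. The 5 genes (2210010C04Rik, Ctrl, Gp2, Reg2 and Try10) were picked by the same replicate contrast, so they are not independent of the enzyme genes. Of 27 measured islet endocrine genes, 0 were among the 17. No whole pancreas was measured, the islet arrays stand in for it, and no biological explanation was tested.

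Brain replicate 1 held Gh at 11.004 and Prl at 7.52, against 7.62 and 5.80 for Gh and 4.65 and 4.48 for Prl on the other brain arrays. Noise of 1 probe set is argued against, since Prl there lay 2.94 log2 units above the highest array outside pituitary and brain. The share of pituitary tissue needed, set against the other brain arrays, was 10.2% for Gh, 1.05% for Prl, 0.356% for Dlk1, 0.260% for Cga, 0.131% for Pomc and 0.0217% for Fshb. The largest share over the smallest, raised by 2 residual SDs, was 102 with the other 11 tissues as baseline (where Dlk1 was not raised, with a share of -0.398%), 50.1 with the other brain arrays, 11.9 for genes above the table median on brain replicate 1 (Gh, Prl and Dlk1), and 1.23 without Gh, whose pituitary signal (14.23) is near the top of the table. Pituitary tissue in the sample, a part of the gland rich in growth hormone cells, and transcription in brain therefore stay open, and the last 2 were not tested.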

How the results depend on the processing

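The alternative without 5 arrays that carry markers of another tissue (brain 1, small intestine 1 and 3, thymus 1 and lung 2) was chosen after the data were seen, and arrays with weaker such signals were kept. It leaves a lone small intestine array, assumed to vary like the other groups, and gave totals of 5206 selectively high and 515 low genes. In islets 12 genes were low, all among the 16, and in brain 55.

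Counts moved by over 1.5 times with the minimum difference, which by construction admits more or fewer genes. At 1.5-fold the total low was 1472 and islets low 67 (total high 7774), and at 4-fold the total high was 2561, the total low 41 and islets low 3. Genes low in pituitary fell from 2 to 1 with each array's median subtracted. Leaving out 1 array gave 1 to 2 genes there, with 1 without islets replicate 3 and without pituitary replicate 1, because Rras2 lies at the threshold.

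The other counts stayed within 1.5 times of their value. Leaving out 1 array gave totals of 5200 to 5237 high and 475 to 521 low, 13 to 17 low in islets, 37 to 57 in brain and 325 to 366 in testis. Subtracting array medians gave 24 low in islets and 274 in testis, and quantile normalisation 21 and 294. Array weights gave 12 low in islets and 61 in brain. With replicate number as a block the totals were 5217 and 498 and islets low 14. Residuals of arrays with the same number had a mean r of 0.0112 and a range from -0.194 to 0.255, and 17 of 39 arrays matched best with their own number, so the numbers were not taken to pair the arrays.

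With an estimated correlation, 65 of 111 list calls were lost and 46 kept. Among the lost calls were immediate early and stress genes in adipose tissue (camera adjusted p = 0.328) and islets (0.323) and macrophage in islets (0.196). So were proliferation (0.0993) and fatty acid oxidation in brain (0.0835), glycolysis in liver (0.269), B cell in lung (0.108) and endothelium in testis (0.129). Preset camera assumes nearly uncorrelated genes, and the estimate widens the null. Fry, which asks another question, lost 0 calls and added 42, including brown adipocyte in adipose tissue (7.09e-05).

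Calls held for 65 of 65 named high genes and 48 of 48 pair genes in every alternative rerun for them, and for 33 of 35 low genes, the exceptions being Mmp14 and Rras2. No result reversed. Signals near background limit dim genes: without genes whose highest tissue mean lay below 6.41, 5061 high and 505 low genes were found.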

Other observations

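Some genes marked a tissue by a high level and another by a low level. Of 5685 genes selectively high or low in any tissue, 39 were high in 1 tissue and low in another. Examples chosen after their values were seen are Mme, a membrane protease, high in small intestine and low in islets, Agpat2, of lipid synthesis, high in adipose tissue and low in brain, the endothelial gene Pecam1, high in lung and low in testis, and the transferrin receptor gene Tfrc, high in placenta and low in testis.

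Sex-linked genes divided the placenta arrays. Xist measured 10.57, 10.54 and 7.61 on placenta replicates 1, 2 and 3, and tissue means elsewhere lay between 4.23 and 5.16. Eif2s3y, on the Y chromosome, measured 4.16, 4.04 and 7.87 on the same arrays, Kdm5d 5.36, 4.85 and 7.24, and Uty 4.65, 4.37 and 6.99. Eif2s3y means lay between 8.40 and 9.60 in the other tissues except testis, where it measured 6.56 ± 0.54. Testis also stood at 5.26 for Kdm5d and 5.59 ± 0.36 for Uty. Xist was selectively high in placenta and is among the 320 genes counted there. The labels give no sex, so in the placenta calls a difference in sex cannot be told apart from a difference of tissue.

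Several arrays held transcripts typical of another tissue or, for B cell genes in small intestine, of a cell type that any tissue may hold. In thymus, Ucp1 measured 7.62, 5.01 and 6.01 and Cidea 8.89, 5.45 and 6.43 on replicates 1, 2 and 3, and the mean of the brown adipocyte list 6.86, 5.67 and 6.11. In lung, Myh6 measured 7.22, 8.87 and 6.79 and Tnnt2 7.74, 8.85 and 7.47. In small intestine, Ms4a1, a B cell gene, measured 4.79, 4.41 and 7.59, with the mean of the B cell list at 6.00, 5.79 and 7.18. Weaker signals of another tissue stood on heart replicate 3 (Ucp1 6.70 against 5.01 and 5.30, Adipoq 6.475 against 4.74 and 4.61), muscle replicate 1 (Adipoq 7.74 against 6.76 and 6.57) and brain replicate 2 (Gh 7.62). These genes were chosen after their values were seen.

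Other values differed between arrays of a tissue. The immediate early gene Egr1 was higher on replicate 1 than on replicate 3 in 13 of 13 tissues, for example with 9.48 and 7.57 in adipose tissue, 9.93 and 7.84 in liver and 8.59 and 6.875 in kidney. Fos was so in 10 of 13, and the mean of the immediate early and stress list in 11 of 13, with the widest range in adipose tissue (9.31, 8.51 and 7.84 on replicates 1, 2 and 3). These genes were chosen after their values were seen. Of all 19938 genes, 4 stood higher on replicate 1 than on replicate 3 in every tissue and 3 lower, where chance gives 2.43 each if the tissues are independent. The slow muscle list averaged 9.89, 10.83 and 10.56 on the muscle arrays.

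Among selectively high genes, the nearest tissue for muscle was heart in 85 genes (45.0%), for thymus small intestine in 99 (27.6%) and for islets pituitary in 37 (22.8%).

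The counts of selective genes were compared with 100 groupings of the 40 arrays into groups of the same sizes, the real one included. These groupings mix tissues, which widens the spread within groups, so what they can exclude is chance in the sense of arrays put together without regard to tissue, and they say nothing on the size of a single tissue's count, such as 2 genes low in pituitary. In that sense chance can be excluded for the genes selectively high in total (5219, highest other 183), for genes selectively high in islets (162, highest other 151) and liver (311, highest other 78), and for those in pituitary (100, highest other 183), where 2 of the 100 groupings gave a count as large. The highest other was 0 for genes selectively high in adipose tissue (181), brain (748), muscle (189), heart (144), kidney (238), lung (251), placenta (320), small intestine (423), testis (1793) and thymus (359), and for genes selectively low in total (505) and in adipose tissue (2), islets (16), brain (42), muscle (24), liver (32), pituitary (2), placenta (8), small intestine (8), testis (356) and thymus (15). There 1 of the 100 groupings, the real one, gave a count as large, but as the others called no gene the comparison adds little. The groupings with 183, 151 and 78 genes were those that drew all 3 lung arrays, all 3 liver arrays and 3 of the islet arrays into 1 group, so these counts come from the structure of the samples.

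For islets against pituitary, 1980 genes were called in both directions, and the highest other count was 1290. The real split was thus the 1 of the 35 splits of the pair's 7 arrays with as many. All other splits mix islets and pituitary, which widens the spread within groups and favours the real split. Only arrays put together without regard to tissue are thereby excluded, and nothing is said on single calls. For heart against muscle (2073, highest other 2) and liver against kidney (2567, highest other 1) the 10 splits are too few for a share under 0.05.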
